A study of Mus musculus with 6 samples.

How the data were processed

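The series holds 1 RNA, 1 hashtag and 1 TCR library for each of 2 antigens, from tetramer-sorted lung CD8 T cells of 10 pooled mice. Reads were processed with Cell Ranger 3.1.0 against mm10 (GRCm38), and cells were analysed with Seurat 3.2.2, per the submitters' processing notes and the matrix header. The deposited RNA and hashtag matrices hold UMI counts, and the TCR contig tables hold UMI counts per contig, per the file headers. The RNA matrices list 737280 barcodes and 31053 genes per library. The authors' normalized tables hold the natural log (ln) of 1 plus 10000 times a count over the cell's total, which matched the raw counts within 2% in 99.98% of SIIN and 99.92% of SIY values checked. These tables list 5656 SIIN cells (median 3992 UMIs) and 3187 SIY cells (median 3215 UMIs) and served as the authors' cell list. Their highest mitochondrial shares were 4.998% and 4.963%, and their highest gene numbers 3991 and 3997. The normalized hashtag tables were not used here, since the raw counts were.

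Hashtags, named MB and a number, were taken to mark mice, and the same hashtag in both libraries the same mouse, since the labels' protocols put labelling before sorting. They were called with Seurat 5.3.0 (HTODemux, positive quantile 0.99). In SIIN this gave 3601 single, 1633 multiple and 422 cells without hashtag counts, and in SIY 1403, 1326 and 458. Cells called multiple were treated as doublets and left out, as they had been from the authors' TCR assignment table. A ratio rule (top hashtag at least 10 counts and 3 times the next) kept 4499 and 2505 cells and served as an alternative. The single-hashtag cells were 80.0% (SIIN) and 56.0% (SIY) of that number, and the gap was unequal between mice. MB9622 kept 198 SIIN and 151 SIY cells, against 564 and 573 by the ratio rule. MB9625 kept 315 SIY cells against 678. The hashtags and their pairing were checked in 3 ways. Sex-linked transcripts matched in all 10 pairs (4 male, 6 female). A mouse's own SIY profile was the best match of its SIIN profile in 7 of 10 mice, with own-pair correlations from 0.00945 to 0.410. Of cells in beta-chain clones of at least 5 cells, 99.0% (SIIN, 48 clones) and 93.8% (SIY, 44 clones) carried their clone's main hashtag. That check was made within each library, so it bears on hashtags marking mice and not on the pairing between libraries.

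Raw counts were summed per mouse and library over mice with at least 20 cells (10 per gate) for both antigens. Genes were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM, filterByExpr) with mouse as a block, and Benjamini-Hochberg adjusted p of 0.05 as threshold; DESeq2 1.42.0 was run beside it. Gates used cells thinned to 1800 UMIs, the percentile 10 of the shallower library rounded down, which left out 249 SIIN and 131 SIY cells. The same thinned cells gave shares of cells with a UMI. A total of 22 gene lists was fixed, and those with at least 3 tested members were tested with limma 3.58.1 by camera (correlation 0.01, prior count 2), with an estimated correlation and by fry. Members were also counted as adjusted over the list alone. Genes were named by a fixed rule: among called genes of at least 20 CPM with 1 direction in at least 80% of mice, the 10 largest changes each way, plus up to 4 members per list with the smallest p, leaving out receptor segments, unnamed models, ribosomal genes and, outside the lists, mitochondrial genes.

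Cells of both libraries were clustered together in scanpy 1.11.5 (10000 counts per cell, 2000 variable genes without the listed genes, 30 components, 15 neighbours, Leiden resolution 1.0 with leidenalg 0.10.2). A cluster took a class name when at least 3 markers of that class, and no fewer than of any other, were 1.5 times higher than in the other cells and seen in at least 5% of its cells. Its 10 leading genes also had to hold markers of that class, at least 3 times as many as of any other, and its cells could not be much shallower than their library. That rule was tightened after the cluster tables were seen and before any group was tested. The family of 5 named classes was chosen as the main one after the results by cluster number were seen, and both are given. Clonotypes were those of the authors' assignments. Shares, clonality and V segments (mean share of at least 5% in 1 library) were compared by exact two-sided sign-flip permutation over mice, adjusted over each family; 10 mice allow 0.00195 at the smallest.

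Free RNA was estimated from barcodes of 1 to 50 UMIs. These barcodes held 226952 of 35924353 UMIs in SIIN and 1827702 of 16700849 in SIY, so this background was larger in the SIY library. A first estimate gave values over 100% for SIY and was replaced, after that was seen, by one from sex-linked transcripts in mice of the other sex. It gave 0.938% for SIIN (95% interval 0.595 to 1.41, 23 UMIs) and 2.50% for SIY (1.01 to 5.15, 7 UMIs). scrublet called 3 SIIN cells (0.083%) and 9 SIY cells (0.641%), too few in SIIN to be of use. Per-mouse RNA sums ran from 128496 to 3869532 UMIs in SIIN and 150770 to 1442407 in SIY.

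The tests were run on simulated data. Over all cells, 100% of genes changed by 2-fold and 100% changed by 4-fold were recovered (6451 genes, 3.85% of calls false). The recovered shares were 68% and 99% in the Tcf7 gate, 83% and 99% in the Havcr2 gate, and 16% and 78% for the interaction. Simulated genes had the spread usual for genes of their abundance, so genes that vary more between mice were not represented. For such genes the lack of a call does not exclude a 2-fold change. The sign-flip test called 3% of simulated sets with no shift, 81.8% at 1 SD and 100% at 2 SD. The samples, comparisons, lists, naming rule and first set of alternatives were set before the data were examined. Alternatives varied the test, size factors, low-count filter, block, mice, depth, hashtag call, doublets, gates and clustering. Further ones, chosen after seeing the data, left out the largest clonotypes or stress-gene clusters, counted each clonotype once, capped cells at 30 per mouse and library, or loosened the gates. Gene positions were not used here. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.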

Results

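The data came from KP LucOS mice, in which a lentivirus carrying Cre starts lung adenocarcinomas that express the antigens SIINFEKL (SIIN) and SIYRYYGL (SIY). Lungs of 10 mice were taken 5 weeks after tumor initiation, and suspensions were labelled with hashtag antibodies. CD44-positive CD8 T cells binding a SIIN or a SIY tetramer were sorted and captured for 5′ single-cell RNA sequencing with T cell receptor (TCR) libraries. Each antigen had 3 libraries (RNA, hashtags, TCR), so the series holds 6 samples. The SIIN RNA library held 35924353 UMIs and the SIY RNA library 16700849. Cells with 1 hashtag numbered 3601 for SIIN (median 3629 UMIs, 31 to 765 cells per mouse) and 1403 for SIY (median 3191 UMIs, 46 to 315 cells per mouse). A TCR clonotype was assigned to 81.7% of these SIIN cells and 79.5% of these SIY cells. Comparisons were made within mice, as SIY minus SIIN, and every test was two-sided. Each antigen had 1 RNA library, so a difference between antigens and one between captures cannot be told apart.

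The first question was how gene expression differed between the responses to the 2 antigens in the same tumors. Among receptors and killing molecules, SIY cells had less Havcr2 (TIM-3, an inhibitory receptor of exhausted cells), which fell from 119 to 60.0 library-scaled counts (CPM) with a log2 fold change of -0.90 ± 0.09 (SE, 10 mice; adjusted p = 2.43e-10, lower in 10 of 10 mice). The pore-forming Prf1 fell by 0.83 ± 0.10 on the log2 scale (172 to 95.4 CPM, adjusted p = 5.65e-07, 10 of 10 mice), and Entpd1 (CD39) by 0.73 ± 0.17 (48.9 to 28.2 CPM, adjusted p = 0.00498, 9 of 10 mice). Eomes, a transcription factor of exhausted and memory CD8 T cells, fell by 1.68 ± 0.27 (33.2 to 8.17 CPM, adjusted p = 0.000184, 10 of 10 mice). Itgae, the CD103 integrin chain that binds E-cadherin on epithelium, rose by 1.22 ± 0.16 (56.5 to 122 CPM, adjusted p = 0.000184, 9 of 10 mice). Klf2, which drives the egress receptor S1pr1, rose by 1.66 ± 0.29 (44.7 to 118 CPM, adjusted p = 0.00712, 9 of 10 mice), and S1pr1 itself by 1.03 ± 0.23 (adjusted p = 0.00308, 7 of 10 mice). Il7r, the receptor for a survival cytokine, rose by 0.49 ± 0.07 (181 to 265 CPM, adjusted p = 2.16e-06, 10 of 10 mice).

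In all, 463 of 6451 tested genes differed, 256 higher and 207 lower in SIY; 1232 passed an unadjusted p of 0.05, and DESeq2 called 327. Among those with the largest rises were Mpnd (1.49 ± 0.18), the SMC5/6 subunit gene Nsmce4a (1.42 ± 0.10), the phosphatase subunit gene Ppp1cc (1.27 ± 0.07), the TNF family ligand gene Tnfsf14 (1.11 ± 0.20) and the corepressor gene Ctbp1 (1.11 ± 0.08). Unc119 (1.07 ± 0.15) and Pgrmc2 (1.06 ± 0.16) rose as well. Among genes that passed the naming rule, the largest fall was in Sh3bgrl3, from 1621 to 474 CPM (-1.76 ± 0.06, adjusted p = 2.45e-25, 10 of 10 mice). The replication-linked histone gene Hist1h2ap (-1.69 ± 0.25), Pclaf (-0.97 ± 0.26) and Rrm2 (-0.92 ± 0.23), a ribonucleotide reductase subunit gene, fell, as did Ncdn (-0.89 ± 0.22), the costimulatory ligand gene Cd80 (-0.86 ± 0.15), Diablo (-0.75 ± 0.19) and the NK receptor genes Klre1 (-0.75 ± 0.15) and Klrc1 (-0.34 ± 0.06). The mitochondrial transcript mt-Atp8 fell by 0.67 ± 0.05 (979 to 612 CPM) while mt-Atp6 rose by 0.46 ± 0.04 (2840 to 3907 CPM), each in 10 of 10 mice.

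**Figure D1:**
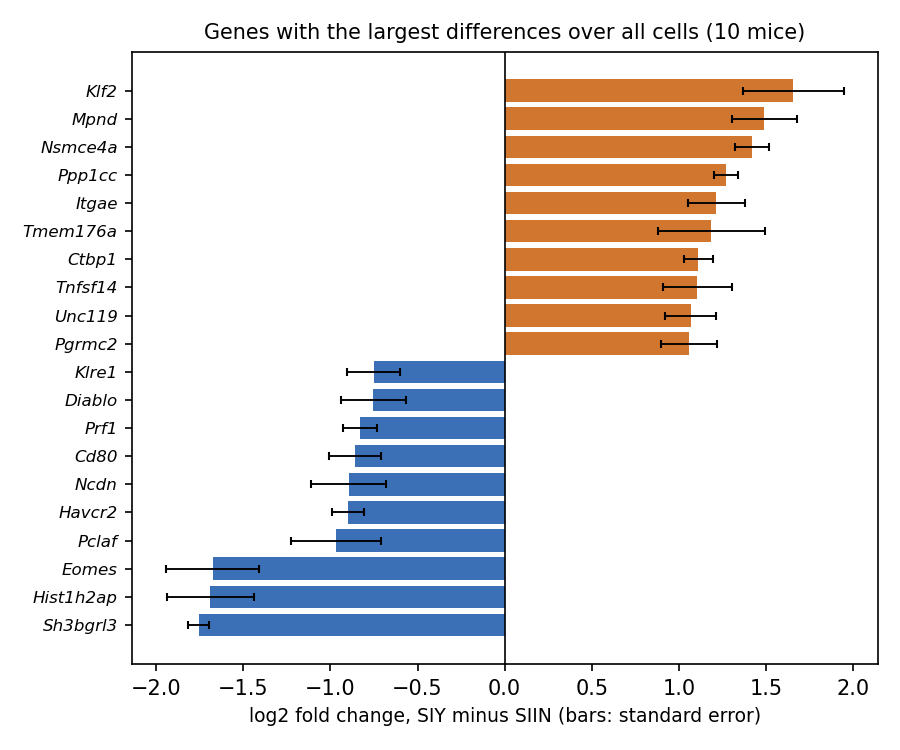
Log2 fold changes (SIY minus SIIN, horizontal axis) of the 20 named genes with the largest changes over all cells; bars are standard errors over 10 mice. Klf2 (1.66) has the largest rise and Sh3bgrl3 (-1.76) the largest fall.

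The comparison was repeated with fewer cells of expanded clones. Cells without a TCR clonotype stayed in, and some of the authors' clonotypes shared a beta sequence. Cells of the largest clones can therefore remain, and the values below do not show what holds without those clones. Without the largest clonotype of each mouse and library, 481 genes were called over 9 mice, 296 of them shared with the 463. Klf2 was then at 1.66, Itgae at 1.01, Havcr2 at -0.54, Prf1 at -0.38, Il7r at 0.36 and Rora at 0.57, all still called. The call ended for Entpd1 (-0.50, adjusted p = 0.0712), for Nkg7 (-0.13) and for Tmem176a (0.48, adjusted p = 0.119), a gene of type 17 cells that rose by 1.19 ± 0.31 with those cells included (27.3 to 58.5 CPM, adjusted p = 0.0465). With the hashtag ratio rule, Pclaf was at -0.14 and Rrm2 at -0.05, and neither was called. That rule also ended the calls of Tmem176a, Klre1, Entpd1 and S1pr1, and leaving out the stress-gene clusters ended those of Tmem176a, Pclaf, Klre1, Itga4 (-0.38 in all cells) and Nkg7. Leaving out 1 mouse ended the call of Tmem176a for any mouse but MB9561 and MB9622 (1.03 to 1.27), of Il2ra for 5 mice (0.31 to 0.42), of Pclaf for MB9619 (-0.87) and MB9625 (-1.03), and of Nkg7 for MB9457 (-0.29) and MB9621 (-0.31). Without the pairing by mouse 292 genes passed. Eomes (-1.73), Entpd1 (-0.67), Il7r (0.52), Cd160 (0.69), Tnfsf14 (1.02), Klre1 (-0.68) and Klrc1 (-0.35) kept their size there but not their call, as did Tmem176a, Pclaf, Ltb, Itga4, Nkg7, Zfp36 and Il2ra.

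Gene programmes were compared next. The numbers of members called were adjusted over the list alone, whereas the adjusted p given beside a member is over all tested genes. Of 5 tested type 17 (Tc17) genes 3 were higher in SIY, with a list median of 0.79. Rora, a transcription factor of that programme, rose by 0.76 ± 0.11 (49.1 to 87.4 CPM, 10 of 10 mice). Tmem176b, at 1.05 (adjusted p = 0.0744), passed over the list alone only, and Ramp1 was at 0.79 (adjusted p = 0.286). Of 8 progenitor genes 3 were higher (median 0.39), with Il7r and Ltb (0.27) called over all genes. Tcf7 (TCF1), at 0.42 ± 0.14 (30.4 to 37.8 CPM, adjusted p = 0.0622), passed over the list alone only, and Slamf6 was at 0.36 (adjusted p = 0.278). Of 16 exhaustion genes 4 were lower and 1 higher (median -0.25): Havcr2, Entpd1 and Eomes fell while Cd160 rose by 0.66 ± 0.13 (adjusted p = 0.00113, 7 of 10 mice). Of 5 NK receptor genes 2 were lower (median -0.23), with Klrk1 at -0.21 and Klrd1 at -0.23, and of 11 cell cycle genes 2 were lower (median -0.23), with Mki67 at -0.55 (adjusted p = 0.302) and Top2a at -0.48 (adjusted p = 0.147). camera with a preset correlation called these 5 lists, giving adjusted p = 0.00434 for Tc17, 0.0111 for exhaustion, 0.0208 for progenitor, 0.0262 for NK receptors and 0.0262 for cell cycle. None of the 5 held with an estimated correlation, where Tc17 had adjusted p = 0.321 and the other 4 adjusted p = 0.468. fry, which asks whether a list moves one way on balance, gave adjusted p = 0.0274 for Tc17, 0.107 for exhaustion, 0.122 for progenitor, 0.0570 for NK receptors and 0.144 for cell cycle.

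The other lists were not called by camera (adjusted p of 0.159 or more). Adjusted over the list alone, 3 effector genes were higher and 5 lower of 11, and 2 cytotoxicity genes were lower of 12; Nkg7, a granule gene, fell by 0.30 (3252 to 2670 CPM, adjusted p = 0.0194), and Gzmk was at -0.86 (adjusted p = 0.170). Of 11 cytokine genes 2 were higher and 1 lower, with Tgfb1 up by 0.46 ± 0.09 (adjusted p = 0.00148), Ccl5 at -0.68 (adjusted p = 0.0616) and Ifng at -0.59 (adjusted p = 0.159). Of 9 residency genes 1, Itgae, was higher, and Ccr8 was at 0.54 (adjusted p = 0.111). Immediate early and heat shock genes had 4 of 13 higher, among them Jund (0.37) and Zfp36 (0.42). Glycolysis genes had 1 higher and 3 lower of 12, and mitochondrially encoded genes 6 higher and 2 lower of 13. No member of the TCR activation or interferon-stimulated list passed, where Myc was at 0.50 (adjusted p = 0.113), Egr2 at 0.26 (adjusted p = 0.357), Isg20 at 0.23 (adjusted p = 0.120) and Zbp1 at -0.25 (adjusted p = 0.201). Among genes of other cell types, Cd74 of B cells was at 0.95 (adjusted p = 0.236), Cst3 of myeloid cells at 0.01 (adjusted p = 0.986), Napsa of lung epithelium at -0.09 (adjusted p = 0.859), and the gamma-delta segments Tcrg-C2 and Tcrg-C4 were at -0.43 (adjusted p = 0.0582) and -0.99 (adjusted p = 0.165), with 2 of 2 lower when adjusted over their list alone. Il2ra, from the CD4 T cell list, rose by 0.42 (adjusted p = 0.0278, 6 of 10 mice), a call that ended in thinned sums (0.41). Of 2 NK cell genes 1, Eomes, was lower, and no stromal or erythrocyte gene was abundant enough to be tested.

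Cells with a Tcf7 UMI and no Havcr2 UMI, a usual gate for progenitor-like cells, were compared in the 3 mice with at least 10 such cells for both antigens. The gate need not hold progenitor-like cells only. Tcf7 was also a leading gene of a cluster led by Cd7, Klf2 and S1pr1, which carried 5 progenitor-like and 4 effector-like markers. How many gated cells lay in that cluster was not tested. In this gate Klf2 rose by 2.32 ± 0.58 (36.2 to 186 CPM, adjusted p = 0.0121), and the proliferation-linked genes Hmgb2 and Tubb5 by 1.27 ± 0.24 (268 to 685 CPM, adjusted p = 0.000608) and 0.86 (adjusted p = 0.0314). Nrn1, a gene of anergic T cells, fell by 2.51 ± 0.29 (606 to 107 CPM, adjusted p = 8.37e-10), and Sh3bgrl3 (-1.88 ± 0.20), Srsf3 (-1.11), Txnip (-0.98) and Nkg7 (-0.53, adjusted p = 0.0421) fell too. Rap1b (1.15) and Ppp1cc (1.42) rose. Each named change had 1 direction in 3 of 3 mice. In all 17 of 1043 genes differed, 6 higher and 11 lower, with 76 at an unadjusted p under 0.05 and 3 by DESeq2. Il7r was at 0.58 (adjusted p = 0.976), Xcl1 at -1.47 (adjusted p = 0.976) and Lag3 at -0.60 (adjusted p = 0.192). Adjusted over the list alone, 2 of 2 cell cycle genes were higher and 2 of 6 cytotoxicity genes and 1 of 7 exhaustion genes lower, and no member of the 7 progenitor genes passed. camera called no list here (lowest adjusted p = 0.328), while fry called the 3 tested NK receptor genes lower (adjusted p = 0.0233). Gating without thinning, at 4 or more cells per mouse and library, put Hmgb2 at 0.33, Tubb5 at 0.27, Nrn1 at -0.77 and Srsf3 at -0.22, none of them called. With the progenitor-like class of the clustering that kept listed genes as gate, in 5 mice, Hmgb2 (-0.026) and Tubb5 (-0.033) turned direction and were not called. Sh3bgrl3 and Nrn1 were called whichever of the 3 mice was left out. Without MB9561, 6 genes were called, and Klf2 (2.05), Ppp1cc (1.27), Rap1b (1.08), Srsf3 (-0.88), Txnip (-0.87) and Nkg7 (-0.41) were not among them. Without MB9625 the calls of Klf2 (2.68), Hmgb2 (0.80) and Tubb5 (0.81) ended, and without MB9452 those of Ppp1cc (1.13), Tubb5 (0.53) and Srsf3 (-1.10).

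In Havcr2-positive, Tcf7-negative cells, the terminally exhausted-like gate, 5 mice had enough cells. The activation marker gene Ly6a (Sca-1) rose by 1.61 ± 0.31 (62.2 to 194 CPM, adjusted p = 0.00793) and Ramp1, a CGRP receptor subunit gene, by 1.501 ± 0.27 (84.6 to 273 CPM, adjusted p = 0.000916, 4 of 5 mice). Rgs10 (1.53), Ctbp1 (1.49), Ppp1cc (1.4), the cathepsin gene Ctss (1.11), Snf8 (1.02), Rab2a (1.02), the interferon-induced Isg20 (0.99, adjusted p = 0.0323) and Sla (0.97) rose, as did the lymphotoxin gene Ltb (0.49, adjusted p = 0.0197, 5 of 5 mice). Sh3bgrl3 fell by 1.455 ± 0.11 (1694 to 634 CPM), the stress factor Atf5 by 1.28 ± 0.33 (90.7 to 32.5 CPM), and Hist1h1e (-1.44), Kdm2b (-1.32), the mitophagy kinase gene Pink1 (-1.31), Nme2 (-0.92), Eef2 (-0.42) and H2-D1 (-0.35) fell. Each of these changes had its direction in at least 4 of 5 mice. Ramp1 was also a leading gene of the Tc17-like class of the clustering, which came mainly from MB9619 and MB9622, both among these mice. How many gated cells belonged to that class was not tested. In all 53 of 2280 genes differed, 27 higher and 26 lower, with 284 at an unadjusted p under 0.05 and 20 by DESeq2. Ctla4 was at 0.72 (adjusted p = 0.214), Cxcr6 at 0.33 (adjusted p = 0.0848) and Rgs1 at 0.48 (adjusted p = 0.0933). Adjusted over the list alone, 3 of 4 interferon-stimulated genes and 2 of 6 residency genes were higher, and no member of the 11 exhaustion genes passed. camera called no list (lowest adjusted p = 0.265). With the ratio rule Ly6a was at 0.52, Ramp1 at 0.26, Ctss at 0.37, Isg20 at 0.39, Hist1h1e at -0.45 and Pink1 at -0.70, none called. With the exhausted-like class of the clustering as gate, in 4 mice, 39 genes were called, 17 of them among the 53. The calls of Ly6a (1.25), Ctss (0.44), Snf8 (1.03), Isg20 (0.34), Sla (0.25), Hist1h1e (-0.46), Pink1 (-0.46), Nme2 (-0.58) and H2-D1 (-0.30) ended there. Gating without thinning and at 4 or more cells, in 9 mice, gave 70, with 24 among the 53, and ended the calls of Ly6a (1.10), Ctss (0.15), Isg20 (0.32), Sla (0.55), Atf5 (-0.67), Pink1 (-0.65), Nme2 (-0.35), Eef2 (-0.22) and H2-D1 (-0.25). Leaving out 1 mouse at a time, Rgs10, Ctbp1, Ppp1cc, Sh3bgrl3, Nme2, Eef2 and H2-D1 were called in 5 of 5 fits, Ly6a in the 4 and Ramp1 in the 3 that tested them, and Kdm2b and Pink1 in none of 4. Without MB9561, 26 genes were called, without Snf8 (1.04), Rab2a (0.99), Isg20 (0.98), Hist1h1e (-1.32) and Ltb (0.43). Without MB9619, 32 were called, without Snf8 (0.99), Isg20 (0.86), Sla (0.91) and Ltb (0.35). Calls also ended without MB9452 for Ctss (0.72), Isg20 (1.03), Sla (0.67) and Atf5 (-1.27), without MB9622 for Sla (0.90) and Atf5 (-1.11), and without MB9625 for Rab2a (0.73).

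Whether the antigen difference itself depended on the gate was tested as an interaction in 3 mice. It passed for 3 of 1928 genes, with 77 at an unadjusted p under 0.05 and 2 by DESeq2. Hmgb2 had an interaction of 1.81 ± 0.33, since it rose from 268 to 685 CPM in the Tcf7 gate and went from 394 to 268 CPM in the Havcr2 gate. Ifi27l2a, an interferon-induced gene, had -1.45 ± 0.25, with 917 CPM for both antigens in the Tcf7 gate and 409 against 1134 CPM in the Havcr2 gate. The third, the TCR segment Trbv17 (-5.58 ± 0.55), lies outside the rule for naming genes and was named after its values were seen. Gating without thinning and at 4 or more cells, over 9 mice, edgeR called none (81 genes at an unadjusted p under 0.05), Hmgb2 was at 0.99 and Ifi27l2a at -0.07. With the ratio rule, over 4 mice, none was called either (Hmgb2 1.09, Ifi27l2a -0.37). Without MB9561 Ifi27l2a (-1.42) and without MB9625 Hmgb2 (1.70) lost its call.

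Cells carrying a transcript were then counted after thinning each cell to 1800 UMIs, for 34 fixed measures, so that no measure could pass alone. Havcr2-positive cells made up 13.7 ± 4.45% of SIIN and 8.35 ± 2.59% of SIY cells (mean ± SD, 10 mice; lower in 10 of 10; permutation p = 0.00195, the smallest that 10 mice allow; adjusted p = 0.0221). Prf1-positive cells made up 17.9 ± 4.14% and 10.2 ± 3.32% (lower in 9 of 10 mice, permutation p = 0.00391, adjusted p = 0.0332). Cells with Havcr2 but not Tcf7 fell from 13.6 ± 4.47% to 8.11 ± 3.03%, and cells with neither rose from 82.3 ± 3.82% to 87.6 ± 3.51% (each in 10 of 10 mice, adjusted p = 0.0221). Free RNA alone would give Havcr2 UMIs in 0.253% of SIIN and 0.133% of SIY cells. Almost all Havcr2-positive cells lacked Tcf7, so all of these measures but that of Prf1 are nearly the same result entered repeatedly. The adjusted p values, that of Prf1 included, rest on this repeat, since no measure could pass alone. With that limit, these 4 measures passed. None of them did without the largest clonotype of each mouse and library, over 9 mice, where Havcr2 shares were 12.0% and 8.25% (adjusted p = 0.0996), Prf1 shares 13.9% and 10.2% and shares with neither 85.0% and 88.1% (both adjusted p = 0.228). None did with each clonotype counted once, where the Havcr2 difference was -5.23 ± 9.04 points against -5.39 ± 3.60 (adjusted p = 0.360) and that of Prf1 -5.03 ± 4.93 against -7.69 ± 5.44 (adjusted p = 0.299), so that the Havcr2 call ended with a wider spread and not a smaller difference. Without thinning, Havcr2 shares were 25.6 ± 7.02% and 14.4 ± 5.58%, and Prf1 shares 31.3 ± 4.37% and 19.7 ± 4.60%. Tcf7-positive cells were 4.05 ± 3.38% of SIIN and 4.33 ± 2.71% of SIY cells (permutation p = 0.650, adjusted p = 0.961; free RNA 0.0967% and 0.278%), and 6.98 ± 3.57% and 8.27 ± 4.33% without thinning.

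**Figure D2:**
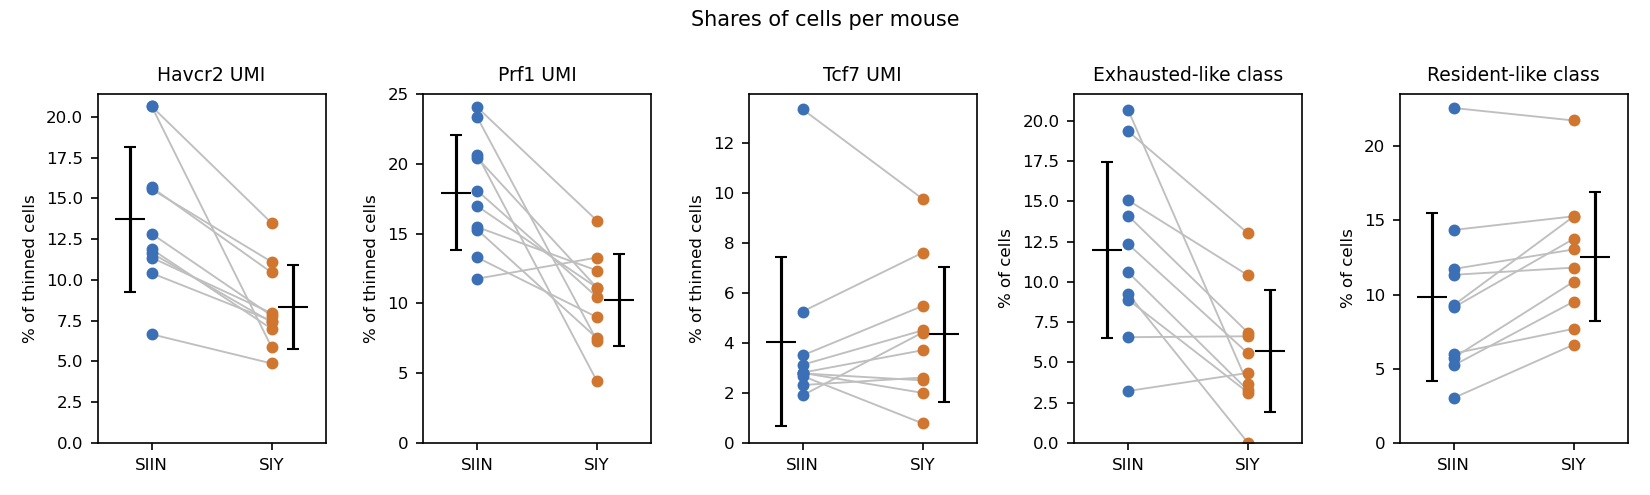
Percent of cells (vertical axes) with a Havcr2, Prf1 or Tcf7 UMI after thinning, and in the exhausted-like and resident-like classes, for SIIN and SIY cells. Points are mice joined by lines and bars are mean ± SD over 10 mice; the Havcr2 share is lower in SIY in 10 of 10 mice.

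Other shares did not pass here, but some did without thinning or with the hashtag ratio rule. Pdcd1 (PD-1) was seen in 48.0% of SIIN and 36.1% of SIY cells (permutation p = 0.0176, adjusted p = 0.0854), or 63.2% and 47.6% without thinning (adjusted p = 0.0133). Itgae was seen in 8.10% and 15.4% (higher in 9 of 10 mice, permutation p = 0.0156, adjusted p = 0.0854; 12.0% and 20.1% without thinning, adjusted p = 0.0369), and Gzma in 2.64% and 6.19% (permutation p = 0.0117, adjusted p = 0.0797; 3.35% and 6.87% without thinning, adjusted p = 0.0332). Thinned values were 7.96% and 4.75% for Entpd1 (adjusted p = 0.0913), 20.03% and 13.5% for Tox (adjusted p = 0.183), 24.97% and 21.4% for Ifng (adjusted p = 0.118) and 22.3% and 27.6% for Il7r (adjusted p = 0.163); without thinning they were 16.8% and 8.25% (adjusted p = 0.0221), 34.6% and 22.7%, 40.2% and 31.9%, and 37.2% and 40.3%. With the ratio rule, after thinning, Il7r (22.4% and 29.7%, higher in 10 of 10 mice, adjusted p = 0.0166), Itgae (adjusted p = 0.0332), Gzma (adjusted p = 0.0415), Entpd1 (adjusted p = 0.0415) and Pdcd1 (adjusted p = 0.0465) passed. Il17a, a cytokine gene of type 17 cells, was seen in 0.512% and 0.721% (0.782% and 0.898% without thinning). Cd8a was seen in 83.4% and 83.1% (free RNA 2.56% and 5.56%) and Cd4 in 0.327% and 0.267% (92.9% and 89.2%, and 0.678% and 0.426%, without thinning).

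Clustering both libraries together gave 12 clusters, 5 of which met the rule for a name. The exhausted-like class, led by Ccl5, Gzmk and Cd244, held 12.0 ± 5.46% of SIIN and 5.68 ± 3.79% of SIY cells (lower in 8 of 10 mice, permutation p = 0.00781, adjusted p = 0.0195). The resident-like class, led by Itgae and Anxa1, held 9.85 ± 5.66% and 12.6 ± 4.37% (higher in 9 of 10 mice, permutation p = 0.00586, adjusted p = 0.0195). The Tc17-like class, with Il1r2, Ramp1, Tmem176a and Tmem176b, held 2.21% and 3.37% (permutation p = 0.195, adjusted p = 0.326). The interferon-like class (Ifit3, Ifit1, Isg15) held 2.32% and 3.01% and the proliferating-like class (Pclaf, Birc5) 1.07% and 0.8002% (both adjusted p = 0.520). Compared by number over all 12 clusters, 3 passed, namely the exhausted-like and resident-like clusters (both adjusted p = 0.0312) and an unnamed cluster led by the amino-acid-response genes Asns and Slc7a5, which held 14.4 ± 2.34% of SIIN and 6.30 ± 3.18% of SIY cells (lower in 10 of 10 mice, adjusted p = 0.0234). At a clustering resolution of 1.4 the exhausted-like difference was 1.83 percentage points, higher in SIY. With listed genes kept it was -1.21 points (adjusted permutation p = 0.469). By unpaired permutation the exhausted-like class still passed (adjusted p = 0.0407) and the resident-like class did not (adjusted p = 0.615). An unnamed cluster led by Xcl1, Ccl1 and Cd160 carried as many exhausted-like markers (7) as the exhausted-like class, beside 6 progenitor-like ones. It held 10.9% of SIIN and 13.0% of SIY cells. With each clonotype counted once the resident-like class held 8.96% and 15.5% (10 of 10 mice) and the exhausted-like difference was -1.61 points. Without the largest clonotype of each mouse and library, over 9 mice, neither class passed (-1.58 points for exhausted-like and 3.46 for resident-like, both adjusted p = 0.176).

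TCR clonotypes were less concentrated in the SIY response. Only cells with a TCR clonotype entered these measures. Of these, the largest clonotype took 54.7 ± 13.1% in SIIN and 27.7 ± 14.4% in SIY per mouse (lower in 9 of 10 mice, permutation p = 0.00977, adjusted p = 0.0137). At equal cell numbers 19.0 ± 10.2 SIIN and 32.1 ± 16.2 SIY clonotypes were expected (higher in 9 of 10 mice, permutation p = 0.00781, adjusted p = 0.0137). The Simpson index, the probability that a random pair of cells shares a clonotype, was 0.334 ± 0.135 and 0.123 ± 0.104 (lower in 9 of 10 mice, permutation p = 0.0137, adjusted p = 0.0137). MB9622 went the other way, with largest clonotypes of 34.4% of its cells with a TCR clonotype for SIIN and 61.5% for SIY. With clonotypes defined by the beta chain alone, the largest took 70.2% in SIIN and 36.3% in SIY over the 10 mice. There 11.5 and 20.3 clonotypes were expected, so some of the authors' clonotypes shared a beta sequence.

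**Figure D3:**
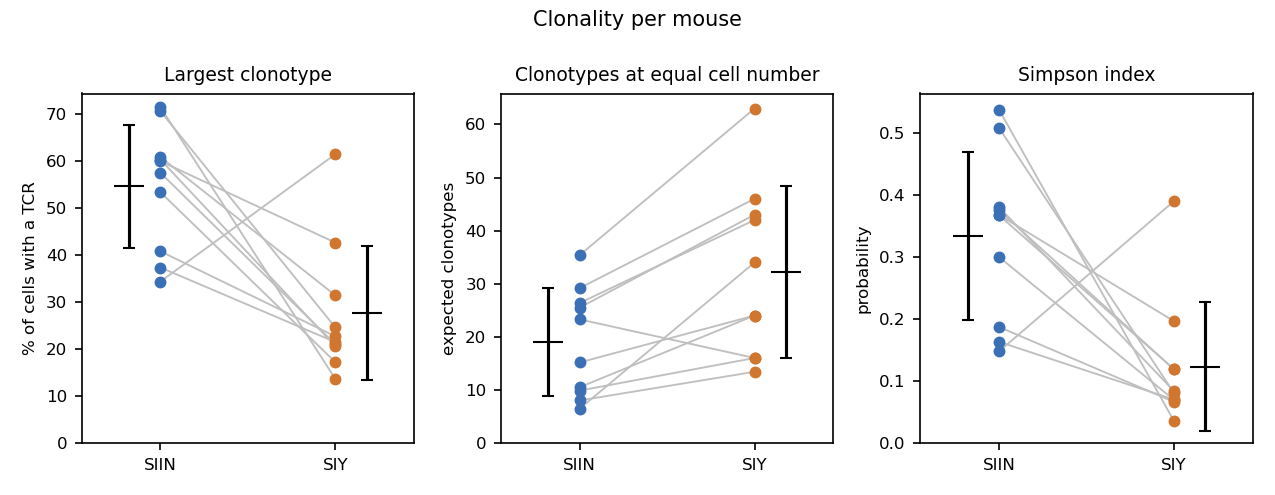
Share of cells with a TCR that lie in the largest clonotype, clonotypes expected at equal cell numbers and Simpson index (vertical axes) for SIIN and SIY cells of each mouse. Points are mice joined by lines and bars are mean ± SD over 10 mice; the largest clonotype averages 54.7% in SIIN and 27.7% in SIY.

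V segments were compared as shares of the authors' clonotypes, each counted once per mouse. Some of these clonotypes shared a beta sequence, so a beta clone could count more than once, and a count by beta sequence was not run. TRBV12-2+TRBV13-2, a joint call of the assembler, made up 3.15% of SIIN and 43.3% of SIY clonotypes (higher in 10 of 10 mice), TRBV16 3.07% and 18.7%, TRBV13-1 5.51% and 14.5% (adjusted p = 0.0184), TRAV8-1 0.222% and 15.6%, and TRAV8D-1 0% and 7.11% (adjusted p = 0.0241). SIIN clonotypes carried more TRBV12-1 (25.2% against 1.17%, lower in SIY in 10 of 10 mice), TRBV14 (13.6% against 1.25%), TRBV31 (11.4% against 0%), TRBV13-3 (6.89% against 1.58%), TRBV15 (6.15% against 0.370%, adjusted p = 0.0409), TRAV14D-2 (11.3% against 0.474%, adjusted p = 0.0241), TRAV6N-7 (8.94% against 0%, adjusted p = 0.0409) and TRAV9D-3 (6.61% against 0%). The adjusted p was 0.0166 for the segments without one given, and 13 of 17 segments passed, each with its direction in at least 6 of 10 mice. As shares of cells 10 passed, without TRBV13-1 (5.28% and 16.4%, adjusted p = 0.228), TRBV13-3 (2.10% and 1.55%, adjusted p = 0.652) and TRBV15 (1.85% and 0.298%, adjusted p = 0.184). Alpha chains came from 250 SIIN and 268 SIY clonotypes and beta chains from 265 and 285. No beta sequence was shared between the libraries (2800 SIIN and 1061 SIY cells with one).

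Clone size was set against phenotype within each library, which no difference between captures can affect. Tcf7-only cells made up 5.57 ± 4.71% of SIIN cells in clonotypes of 1 or 2 cells and 2.87 ± 1.28% in clonotypes of at least 5 (9 mice, exact permutation p = 0.160). The SIY values were 6.60 ± 5.28% and 4.34 ± 3.82% (exact permutation p = 0.297), and 9 mice allow a p of 0.00391 at the smallest. Over 24 further tests by cluster, added after the data were seen, none passed, and with 9 mice no single cluster could have passed alone; the exhausted-like cluster held 6.38% of SIIN cells in small and 16.9% in large clonotypes (permutation p = 0.0117, adjusted p = 0.0938).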

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

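The tests of the weight of deeply sequenced cells and both tests of the Havcr2 share were chosen only after the results were seen. A value in this part stood apart when its gap to the next mouse was too large for its group by Dixon's test. For normally distributed values chance gives about 1 in 20 groups. Many groups here are percentages of few cells or clonotypes, and any value stands apart where all other mice are at 0. The 1 in 20 does not hold for these, so the counts are no measure of an excess over chance. In all 39 of 204 groups had such a value. They were 15 of 64 among UMI shares, 3 of 24 among cluster shares and 7 of 34 among V segments. Among clonality measures 1 of 6 had one, and among CPM values 13 of 76.

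MB9509 gave many of them and had few cells, 31 in SIIN and 46 in SIY. Its SIIN cells had Cd8a in 73.3% of cells, Gzmb in 33.3%, Itgae in 20%, Tcf7 in 13.3% and Tcf7 without Havcr2 in 13.3%, and both Cx3cr1 and Tox in 0%. Its SIY cells had Slamf6 in 12.2% and Tcf7 together with Havcr2 in 2.44%. Its SIIN levels also stood apart for Diablo (46.7 CPM), Hist1h2ap (7.78 CPM) and Klf2 (132 CPM), and TRAV3-3 took 16.7% of its SIIN clonotypes.

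Type 17 genes stood apart in MB9622 and MB9619. MB9622 had Il17a in 2.67% and Il23r in 1.07% of SIIN cells, 14.1% of its SIIN cells in the Tc17-like cluster and 149 CPM of Tmem176a. In its SIY cells a Tc17 gene was seen in 100% of Tcf7-only cells, of which there was only 1, and the Simpson index was 0.390. MB9619 SIY cells had Foxp3 in 4.58% and Il23r in 1.31%. MB9561 SIIN cells had Klrg1 in 3.11%. MB9621 SIY cells lay in the interferon-like cluster in 12.5% and in the Gadd45b and Nr4a3 cluster in 4.17%, with Ctbp1 at 176 CPM and Tnfsf14 at 158 CPM. Klf2 was at 262 CPM in MB9458 SIY and Havcr2 at 113 CPM in MB9625 SIY.

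Among V segments, MB9458 SIY had TRAV10N in 10.7% and TRBV12-1 in 6.45% of clonotypes, MB9561 SIIN had TRAV8-1 in 2.22% and MB9457 SIY in 0%. MB9625 SIIN had TRBV12-2+TRBV13-2 in 20% and MB9452 SIY had TRBV15 in 3.70%. In the Havcr2 gate, MB9452 SIY stood apart for Ctss (362 CPM) and Eef2 (1618 CPM), MB9622 for Nme2 in SIIN (201 CPM) and Snf8 in SIY (22.01 CPM), and MB9619 SIIN for Pink1 (110.0 CPM).

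By the interaction test in 3 mice, the antigen difference itself differed between gates for Hmgb2 (1.81), Ifi27l2a (-1.45) and Trbv17 (-5.58). None of the 3 was called with the hashtag ratio rule (4 mice) or without thinning at 4 or more cells (9 mice).

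Swaps of the library labels within mice were too few for a share under 0.05 in the gates. The Tcf7 gate gave 17 genes, the most in 1 of its 4 splits, against 2 in the highest other split. The Havcr2 gate gave 53, the most in 1 of 16 splits, against 2, and the interaction 3, the most in 1 of 4 splits, against 1.

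The first pattern is the 463 genes that differed over all cells. Of 512 possible swaps 100 were run, and only 1 of these, the real one, gave as many (the highest other, with 1 mouse swapped, gave 368). This argues against chance over mice for the number of genes, and says nothing on any single gene. The weight of deeply sequenced cells is argued against for the 358 of these genes still tested in thinned sums. Their fold changes kept a median of 0.971 of their size there (95% interval 0.948 to 0.996). The share of calls kept in thinned sums, 36.9%, met a bound written beforehand for depth, but thinning left 8323200 of 20856369 UMIs and reducing the sums alone kept 39.7%, so that count decides nothing. Without the largest clonotypes 63.9% of the calls were kept, and genes higher in SIY were no richer in free RNA than others (difference 0.0123 in log2, 95% interval -0.06 to 0.07) while genes lower in SIY were poorer (-0.27, 95% interval -0.39 to -0.16), values that neither name nor exclude expanded clones or free RNA as part of the cause. With 1 RNA library per antigen, a capture batch and a difference between the responses to the antigens cannot be told apart and both may contribute.

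The second pattern is mt-Atp8 lower and mt-Atp6 higher in SIY, although both reading frames lie on 1 bicistronic mitochondrial mRNA. The log2 ratio of mt-Atp8 to mt-Atp6 was lower in SIY in each of 11 clusters, from -1.63 to -0.90, as a capture or library batch would give, and may come from library preparation. In cells that entered no comparison the difference was -1.11, which separates nothing, since those cells were sorted for the same antigens. A difference between antigens that acts alike on all cells stays open. Sh3bgrl3 (lower in SIY) and Ppp1cc (higher in SIY) were likewise called in the same direction over all cells and in both gates. They were not tested over clusters, and a batch stays open for them too.

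The third pattern is the lower share of Havcr2-positive cells in SIY. Free RNA would give 2.22% of the difference and is argued against as its cause. Cells without a TCR clonotype, which may belong to expanded clones, stayed in when the largest clonotypes were left out. Without the largest clonotypes, over 9 mice, the difference went from -5.79 to -3.78 percentage points (exact permutation p = 0.0117) and no longer passed (adjusted p = 0.0996), with 65.3% of it remaining (95% interval 35.1 to 113). With each clonotype counted once 97.0% remained (95% interval 1.83 to 237; lower in 7 of 10 mice, exact permutation p = 0.102), so expanded clones might carry none or most of it. A capture batch was not separable here either, and the antigen remains an untested explanation.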

How the results depend on the processing

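Tests that left out or recounted clonotypes, capped cells, loosened the gates, left out stress-gene clusters or left out mice for clonality were chosen only after the data were seen. The cause was not tested for the changes below, except where fewer cells, mice or counts enter by construction (thinned sums, the cap at 30 cells, leave-one-out).

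Over all cells 463 genes became 292 with no replicate block, 195 in thinned sums, 706 with the ratio rule and 43 with at most 30 cells per mouse and library, and 357 to 494 when each mouse was left out. In the Tcf7 gate 17 became 3 by DESeq2, 35 with no low-count filter, 11 with no replicate block, 3 in thinned sums, 10 without thinning at 4 or more cells (both changed at once, 10 mice instead of 3) and 7 at 3 cells per mouse and library; leave-one-out gave 6 (without MB9561) to 25. In the Havcr2 gate 53 became 20 by DESeq2, 149 with no filter, 24 with no replicate block, 30 in thinned sums, 39 with the exhausted-like class as gate, 70 without thinning at 4 or more cells (9 mice instead of 5) and 21 at 3 cells; leave-one-out gave 26 (without MB9561) to 51. The interaction's 3 became 14 with no filter, 1 with no replicate block, 1 at 3 cells, 0 with the ratio rule and 0 without thinning at 4 or more cells (9 mice instead of 3); leave-one-out gave 2 to 3. The 5 lists called by camera became 0 with an estimated correlation and 2 with no replicate block (Tc17 and exhaustion, both adjusted p = 0.0358). By fry 2 lists were called, Tc17 over all cells (adjusted p = 0.0274) and, not among the 5, NK receptors in the Tcf7 gate (adjusted p = 0.0233); with no replicate block neither was (adjusted p = 0.201 and 0.442).

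The 4 UMI shares that passed became 9 without thinning, 10 with the ratio rule, 0 with each clonotype counted once and 0 without the largest clonotypes. The 2 classes that passed became 1 with no replicate block, 1 with each clonotype counted once, 0 without the largest clonotypes, 0 at Leiden resolution 0.6, 1 at 1.4 and 0 with listed genes kept. All 3 clonality measures passed in every setting run (leave-one-out 3 to 3).

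Directions reversed as follows, in percentage points. With each clonotype counted once: Tcf7 -0.0793, Slamf6 -0.905, Ccr7 0.858, Il17a -0.404, Ccr6 -2.47, Cd8a 4.73, Trdc -0.328, Tcf7 and Havcr2 together -0.148, Tc17-like class -0.174. Without the largest clonotypes: Ccr7 0.0525, Lag3 1.92, Gzmb 3.09, Il17a -0.141, Cd8a 1.16, Trdc -0.0445, Tcf7 and Havcr2 together -0.175. With the ratio rule: Ccr7 0.559, Il23r 0.0380, Trdc -0.0760, a Tc17 gene within Tcf7-only cells -0.241. Without thinning, Xcl1 was at -0.730 and Cx3cr1 at -3.73; with TCR cells only, Gzmb was at 0.861 and Cd8a at 0.271; at Leiden 1.4 the exhausted-like class was at 1.83. With the progenitor-like class of the clustering that kept listed genes as gate, Hmgb2 was at -0.026 and Tubb5 at -0.033 (log2). For called genes named in the text, 969 values kept direction and call, 223 kept direction only and 2 reversed. With no replicate block 37 of these genes' calls held and 35 did not, by DESeq2 48 held and 24 did not, and with the ratio rule 45 held and 26 did not. For UMI shares 162 values kept direction and call, 8 kept direction only, 23 reversed and 11 passed anew. V segments passed in 13 cases, 10 when cells were counted, and 13 with no replicate block.

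Alternatives without other cell types were not run, since no such cluster was named, nor was the progenitor-like gate of the main clustering. Resolution 0.6 gave no exhausted-like, resident-like or Tc17-like class, and the listed-genes clustering no resident-like class. Only 3 mice had enough cells for the Tcf7 gate and 5 for the Havcr2 gate.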

Other observations

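The tests of clone size by cluster were added after the data were seen. The largest cluster, 1020 cells led by the integrated-stress genes Atf5, Trib3 and Cdkn1a, held 20.3% of SIIN and 29.0% of SIY cells (higher in 9 of 10 mice, adjusted p = 0.158 over 12 clusters). Its cells were shallow (median 2624.5 UMIs), and a TCR was assigned to 56.6% of those from SIIN and 51.6% of those from SIY. A cluster of 664 cells led by Xcl1, Ccl1 and Cd160 carried markers of both progenitor-like (6) and exhausted-like (7) cells and held 10.9% of SIIN and 13.0% of SIY cells. A cluster of 275 cells led by Cd7, Klf2, S1pr1 and Ly6c2, with Ccr2, Tcf7 and Gzmk also among its leading genes, held 5.72% and 7.16%. A cluster of 739 cells with Ifitm1 and Pim2 held 15.6% and 12.9%, and a small one with the activation genes Gadd45b and Nr4a3 (45 cells) 0.811% and 1.34%.

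Tc17-like cells came mainly from MB9619 and MB9622, where they were 6.73% and 14.1% of SIIN cells and 12.5% and 11.3% of SIY cells; no other mouse had more than 0.523% in SIIN or 4.35% in SIY. Their largest clonotype held 32.2% (SIIN) and 27.9% (SIY) of those with a TCR. By clone size, the Cd7 and Klf2 cluster held 12.1% of SIIN cells in clonotypes of 1 or 2 cells against 4.90% in clonotypes of at least 5 (permutation p = 0.0352, adjusted p = 0.141), and 14.6% against 6.30% in SIY (permutation p = 0.0195, adjusted p = 0.0938). The Atf5 cluster held 23.9% against 11.3% in SIIN (permutation p = 0.0156) and 29.3% against 11.1% in SIY (permutation p = 0.0117). A TCR was assigned to only 56.6% and 51.6% of its cells. Whether missing chains put such cells in small clonotypes was not tested. The proliferating-like cluster held 0.271% against 1.51% in SIIN (permutation p = 0.0117). None passed adjustment over 24 tests, and with 9 mice none could have passed alone.

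After thinning, further shares for SIIN and SIY were 36.3% and 32.1% for Lag3, 11.3% and 10.98% for Gzmb, 18.6% and 19.96% for Xcl1 (free RNA alone would give 1.06% and 5.11%), 67.9% and 61.8% for Cxcr6, and 2.88% and 1.30% for Mki67. Without thinning these were 48.0% and 39.4%, 15.2% and 12.7%, 27.0% and 26.3%, 78.9% and 70.8%, and 6.17% and 3.79%. The effector genes Cx3cr1 and Klrg1 were at 7.20% and 7.66%, and 0.686% and 0.174%, and the lymph node homing gene Ccr7 at 1.75% and 1.68%. None of these differences passed in the cells with 1 hashtag after thinning. Without thinning that of Lag3 did (permutation p = 0.00781, adjusted p = 0.0332), and with the hashtag ratio rule that of Xcl1 (18.7% and 21.1%, higher in 9 of 10 mice, adjusted p = 0.0465), where free RNA differs more than the cells do.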
